A study of Homo sapiens with 24 samples.

How the data were processed

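Human U2OS osteosarcoma cells with a tetracycline-off switch for the TOB2 mutant S254D were compared between an uninduced and an induced arm over a bromouridine pulse-chase. Cytoplasmic RNA was taken at 0, 0.5, 1, 2, 4 and 6 h of chase and the bromouridine-labelled part was recovered with an antibody. The 24 libraries fell into 12 groups of arm and time with 2 libraries each, numbered replicate 1 and replicate 2. The labels do not say that the replicates came from separate cultures, so they may be technical.

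The deposited values are TPM, abundances scaled for transcript length and to a fixed total per library, for each RefSeq transcript and with 2 decimals. The submitters' processing notes name Trim Galore, Bowtie2, RSEM 1.3.0 and the hg19 build without giving their roles or their order. The table held 48009 transcripts, of which 3 had no gene symbol and were at 0 in every library. TPM was summed over the transcripts of each symbol, which gave 25341 genes. Genes with a mean of at least 1 TPM over the 24 libraries were kept, which left 13416 genes holding at least 99.8% of the TPM of any library. The values of each library add up to the same fixed total, so the sequencing depth was unknown and no counting error could be given. The table held no spike-in sequences and no entries for mitochondrially encoded genes. Among the genes kept, 46 had values identical to those of another gene in all libraries, which leaves their separate levels uncertain.

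Models were fitted with limma 3.58.1 in R 4.3.3 on log2 of TPM plus a pseudocount of 1, with moderated variances that followed the mean level and no replicate term. A straight line on hours of chase was fitted for each arm in a single model of all libraries, with 20 residual degrees of freedom. It gave the slope of each arm and the slope difference, induced minus uninduced. A second model gave each of the 12 groups its own mean, with 12 residual degrees of freedom. It gave the difference at 0 h and the mean difference over the 6 times, induced minus uninduced. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the genes kept, with a threshold of 0.05. Slopes are relative to the labelled RNA of the same library, since TPM cannot show a loss shared by all RNAs. Genes and values were read with the data.table package, version 1.17.8, and plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

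The spread of slopes across genes was compared between arms as a ratio of variances. Each variance was the covariance across genes of the slopes from replicate 1 alone and from replicate 2 alone, which leaves out noise not shared by the replicates. Its p came from an exact two-sided permutation test over the 4096 swaps of the arm between libraries of the same time and replicate number. The number thus joined the libraries of a slope across times and also limited the swaps. Each library was also placed in hours along the uninduced decay pattern, by the covariance across genes between its change from the uninduced 0 h library of its replicate number and the uninduced slopes of the other replicate. The scale was set so that the uninduced slopes advance 1 h per hour on average.

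There were 27 gene lists, of which 24 had at least 5 genes kept and were tested. Mitochondrially encoded transcripts (0 of 15 measured), osteoblast markers (2 of 10) and leukocyte markers (2 of 11) could not be tested. Lists were tested with limma's camera with a preset correlation of 0.01 between genes, adjusted over the lists of each comparison. Camera with an estimated correlation and fry were run beside it. Fry tests whether the genes of a list move, on balance, in the same direction and does not compare them with other genes. Counts adjusted over the list alone used the genes of that list as the family of tests.

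The comparisons, tests, gene lists, filters, first set of alternatives and the rule for named genes were fixed before the data were examined. TOB2 was named first. For each comparison of slopes or levels, the named genes were the 10 largest positive and the 10 largest negative values among genes past the threshold, with a mean of at least 5 TPM and the same sign in both replicates. If none passed in a direction, the 5 genes with the smallest p were to be named. Each list gave up to 4 members with the smallest p. Not every gene that the rule took is printed.

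Alternatives covered the pseudocount, the filter, scaling by quantile normalization or median-of-ratios, transcripts in place of genes, a replicate term, the variance trend, shorter chases, other contrasts, and leaving out each library or each replicate series. Removal of the 3 most abundant noncoding RNAs, restriction to protein-coding transcripts and swaps not limited by replicate number (random permutations of the libraries within each time) were added after the data were seen. The methods were tested on simulated data with 200 of 13416 genes changed. A slope difference of 0.2 log2 per hour was recovered for 78.5% of those genes and a slope difference of 0.1 for 1.5%. In 1 simulated data set with a true variance ratio of slopes of 1.44, the estimate was 1.421 and the permutation p was 0.1274, so the test of spread missed a widening of that size. A mean difference of 0.6 was recovered for 97.5%, and a 0 h difference of 0.6 for 36.5%. Of the 24 lists, 0 were called by limma's camera in simulated data with no effect, where genes varied independently. Among 99 other splits of the real libraries within each time, which keep the correlation between genes, the median count of lists called was 9 for the slope difference (1 to 16) and 8 for the mean difference (1 to 15).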

Results

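The series followed bromouridine-labelled cytoplasmic RNA in U2OS cells, a human osteosarcoma line, with and without induction of a phosphomimetic mutant (S254D) of TOB2. TOB2 belongs to the BTG/TOB antiproliferative family, whose members bring the CCR4-NOT deadenylase to mRNAs. Doxycycline was in the medium of the uninduced arm and absent from the induced arm, so the drug and the transgene changed together. There were 24 libraries, 12 per arm and 2 for each arm and time of chase. The values were TPM of unknown depth, and between 12594 and 13757 genes reached 1 TPM in a library. A gene with a negative slope became a smaller share of the labelled cytoplasmic RNA, and a loss shared by all RNAs would leave no trace. Labelled RNA that reached the cytoplasm during the chase cannot be separated from loss, so decay and loss below refer to this share.

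The noncoding RNAs RMRP, MIR6723 and RPPH1 made up 22.4% ± 0.346 (SD, n = 2) of the TPM at 0 h and 8.11% ± 0.479 at 6 h in the uninduced arm. RMRP is the RNA of RNase MRP and RPPH1 that of RNase P. MIR6723, at 3.01% to 16.3% of a library, lies in a nuclear copy of mitochondrial DNA, and the table cannot show how much of its value came from mitochondrial reads. In the induced arm their share was 24.3% ± 4.5 at 0 h and 7.34% ± 0.288 at 6 h. Induced replicate 2 held 27.5% at 0 h and 27.5% at 0.5 h, against 21.1% and 19.5% in induced replicate 1. The first principal component held 54.7% of the variance and separated the times of chase from 1 h on, while the induced libraries at 0 h (-40.29 and -36.53) and 0.5 h (-38.13 and -36.49) overlapped. Its mean at 6 h was 58.5 ± 0.714 in the uninduced and 71.1 ± 0.608 in the induced arm (SD, n = 2), against -39.5 ± 0.283 and -38.4 ± 2.66 at 0 h. Pearson's r between the 2 libraries of a group, taken across genes, which are not independent replicates, lay between 0.97 and 0.986.

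TOB2 itself was higher in each induced library than in any uninduced library, at 499 to 725 TPM against 92.3 to 267 TPM. At 0 h its level was 256.6 ± 15.2 TPM in uninduced and 584.9 ± 96.7 TPM in induced cells (SD, n = 2), a 2.28-fold difference. At 6 h it was 98.6 ± 8.9 TPM against 643.7 ± 95.1 TPM, a 6.53-fold difference. TOB2 mRNA fell along the chase in uninduced cells by a slope of -0.21 log2 per hour (SE 0.0268, adjusted p = 4.03e-07). Its slope in induced cells was 0.016 (adjusted p = 0.592), and the slope difference was 0.22 (SE 0.038, adjusted p = 0.00807). The table cannot separate the transgene's reads from those of the cell's own TOB2.

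**Figure D1:**
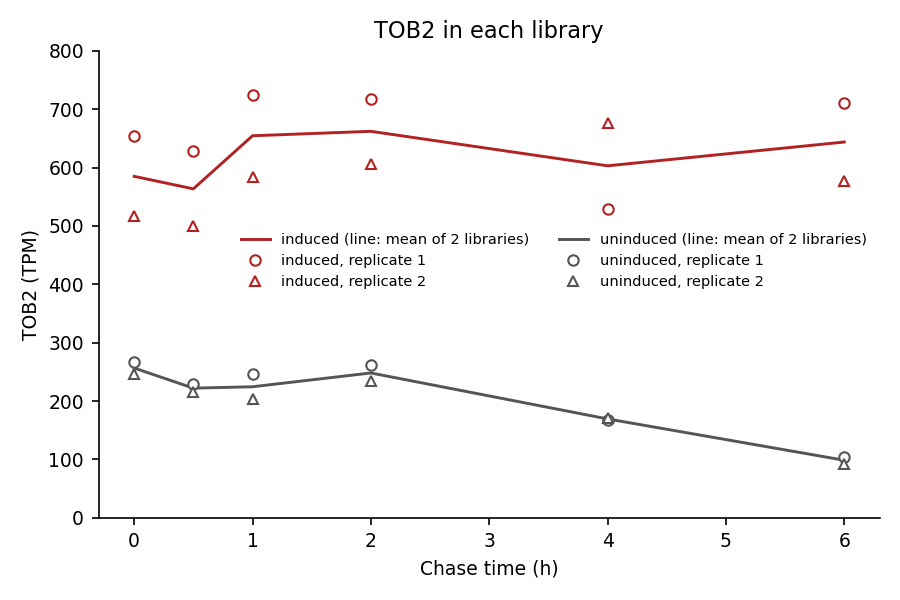
TOB2 level in TPM against hours of chase, with each library as a point and the mean of 2 libraries as a line for the uninduced and the induced arm. Induced libraries lay between 499 and 725 TPM and uninduced libraries between 92.3 and 267 TPM.

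The decay slope in uninduced cells shows which labelled mRNAs fell fastest as a share of the labelled cytoplasmic RNA without induction. Among the lists tested, immediate early and replication-dependent histone transcripts were lost fastest, and most transcripts of the proteasome, ribosome and respiratory chain became a larger share. The calls of the latter 3 lists were lost with an estimated correlation (adjusted p = 0.222, 0.324 and 0.203). JUNB, a component of the AP-1 transcription factor, went from 2251 ± 74.8 TPM at 0 h to 24.2 ± 0.134 TPM at 6 h (SD, n = 2), a slope of -1.10 log2 per hour (SE 0.0262, adjusted p = 4.52e-20). EGR1, a zinc finger transcription factor induced by growth signals, went from 265.8 ± 72 to 4.06 ± 0.184 TPM (slope -0.98, SE 0.0762, adjusted p = 1.57e-10). IER5, another immediate early gene, went from 433.1 ± 55.4 to 7.04 ± 0.148 TPM (slope -0.97, SE 0.0389, adjusted p = 2.18e-15). The transcriptional regulator SERTAD1 (slope -0.94) and IER5L (slope -0.87) also fell. In the other direction, POLR2B, the second largest subunit of RNA polymerase II, went from 32.2 ± 3.01 to 158.4 ± 6.31 TPM (slope 0.41, SE 0.0314, adjusted p = 1.16e-10). ZBED6 (0.43), the RNA-binding factor SRRT (0.41), the readthrough transcript GPR75-ASB3 (0.41) and the splicing-related factors THRAP3 and BCLAF1 (both 0.39) rose as well.

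Short RNAs stood at both ends, where TPM is least certain because the effective length is small. The steepest slopes belonged to SNAR-A1 and SNAR-A2, which share identical values (-1.14, SE 0.321, adjusted p = 0.00329). MIR6077 (-1.11), the small nucleolar RNA SNORD72 (-0.91) and the microRNA host MIRLET7DHG (-0.84) also fell. SNORD84 (0.64), SNORD88A (0.46) and SNORD94 (0.41) rose.

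Of 43 measured immediate early genes, 40 fell and 1 rose (41 and 1 adjusted over the list alone), with a median slope of -0.39 log2 per hour. The member that rose was SRF, at 0.14, which was named after its values were seen. DUSP1, a phosphatase of MAP kinases, went from 2790 ± 38 to 151.6 ± 30.4 TPM, and SPRY4, an inhibitor of receptor tyrosine kinase signalling, from 98.6 ± 0.658 to 8.94 ± 0.693 TPM (SD, n = 2). The list passed camera at an adjusted p of 4.52e-26, and at 0.00123 with an estimated correlation. Of 52 replication-dependent histones, 48 fell and 0 rose (50 and 0 adjusted over the list alone), with a median of -0.33 (adjusted p = 2.33e-37, and adjusted p = 0.0211 with an estimated correlation). Their mRNAs end in a stem-loop and lack a poly(A) tail. HIST1H2BM went from 278.3 ± 5.42 to 34.1 ± 0.813 TPM and HIST1H2AK from 497.6 ± 26.3 to 63.4 ± 16.3 TPM. Of 392 mRNAs of C2H2 zinc finger proteins, 256 fell and 37 rose (258 and 38 adjusted over the list alone), among them ZNF574 at -0.65 and ZNF581 at -0.55. The list passed at an adjusted p of 5.19e-23 but not with an estimated correlation (adjusted p = 0.113).

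Among p53 targets, 16 of 27 fell and 5 rose (the same counts adjusted over the list alone), with the proapoptotic gene BBC3 at -0.49 and the antiproliferative gene BTG2 at -0.68 (list adjusted p = 0.000356, and adjusted p = 0.324 with an estimated correlation). Among mRNAs of cytokines and inflammatory factors with AU-rich elements, 11 of 22 fell and 3 rose, again with unchanged counts adjusted over the list alone. The ribonuclease ZC3H12A (-0.27) and the NF-kB inhibitor NFKBIA (-0.35) fell, and the mitochondrial superoxide dismutase SOD2 rose (0.26). That list passed at an adjusted p of 0.000658, with an adjusted p = 0.291 with an estimated correlation.

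All 31 proteasome mRNAs rose, as PSMD11 did at 0.30 log2 per hour (list adjusted p = 8.81e-10, and adjusted p = 0.222 with an estimated correlation). Of 79 ribosomal protein mRNAs, 75 rose and 2 fell, and RPL5 went from 1076 ± 67.3 to 2849 ± 3.2 TPM (list adjusted p = 1.4e-08, and adjusted p = 0.324 with an estimated correlation). In the list of translation factors with a terminal oligopyrimidine tract, 20 of 22 members rose, as EIF2S3 did at 0.26 (list adjusted p = 2.9e-06, and adjusted p = 0.324 with an estimated correlation). Of 75 nuclear-encoded mRNAs of oxidative phosphorylation, 64 rose and 1 fell, and the ATP synthase subunit ATP5B went from 379.7 ± 10.3 to 1166 ± 48.2 TPM (list adjusted p = 2.26e-07, and adjusted p = 0.203 with an estimated correlation). Glycolytic mRNAs rose in 16 of 18 cases, as PGK1 did at 0.22 (list adjusted p = 0.000126, and adjusted p = 0.324 with an estimated correlation). For each of these 5 lists the counts were the same adjusted over the list alone.

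Mitotic mRNAs rose in 38 of 42 cases, with the transcription factor FOXM1 at 0.33 (list adjusted p = 4.2e-08, and adjusted p = 0.324 with an estimated correlation). Of 44 G1/S and replication mRNAs, 32 rose and 2 fell, with the clamp loader subunit RFC5 at 0.23 (list adjusted p = 0.000126, and adjusted p = 0.435 with an estimated correlation). Of 44 mRNAs of the deadenylation and decapping machinery, 34 rose and 0 fell. CNOT1, the scaffold of CCR4-NOT, went from 40.9 ± 2.12 to 158.4 ± 5.73 TPM, and the poly(A)-binding protein PABPC1 rose at 0.20 (list adjusted p = 1.81e-05, and adjusted p = 0.324 with an estimated correlation). Lysosomal proteins rose in 16 of 18 cases, with LAMP1 at 0.25 (adjusted p = 0.00116, and adjusted p = 0.324 with an estimated correlation). Matrix genes rose in 17 of 22 cases, with the collagen-modifying enzyme PLOD2 at 0.34 (adjusted p = 0.00523, and adjusted p = 0.391 with an estimated correlation). In the endoplasmic reticulum list 17 of 22 rose and 2 fell, with PDIA6 at 0.24 and DNAJB9 at -0.39 (adjusted p = 0.00774, and adjusted p = 0.454 with an estimated correlation). In the cholesterol list 17 of 26 rose and 2 fell, with the synthase HMGCS1 at 0.18 (adjusted p = 0.0256, and adjusted p = 0.539 with an estimated correlation). The counts of these 7 lists were the same adjusted over the list alone.

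In total, 8739 of 13416 genes had a slope past the threshold in uninduced cells, 5746 rising and 2993 falling. In induced cells 9480 did, 5583 rising and 3897 falling. Median-of-ratios scaling moved the median of all uninduced slopes by -0.0544 log2 per hour, or -0.326 over 6 h. It took the rising share from 65.8% to 43.8% in uninduced and from 58.9% to 44.9% in induced cells. Without RMRP, MIR6723 and RPPH1 the shares were 51.8% and 44.7%, and with protein-coding transcripts alone they were 55.5% and 47.0%. No list called here for its uninduced slope changed the sign of its median under quantile normalization, median-of-ratios scaling or removal of those 3 RNAs.

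The slope difference asks whether relative mRNA decay differed between the arms, which differed in the mutant and in doxycycline. ID3, an inhibitor of helix-loop-helix transcription factors, was at 1103 ± 31.4 TPM in uninduced and 1332 ± 35.9 TPM in induced cells at 0 h (SD, n = 2). At 6 h it was at 216.5 ± 32.7 against 67.4 ± 2.75 TPM, and its slope was lower in the induced arm by -0.34 log2 per hour (SE 0.0551, adjusted p = 0.00686). CITED4, a transcriptional coactivator that binds CBP and p300, was at 65.5 ± 2.55 against 17.1 ± 2.02 TPM at 6 h (slope difference -0.27, SE 0.0559, adjusted p = 0.0263). SIX2, a homeobox factor, stayed near its starting level in uninduced cells, at 86.8 ± 3.58 TPM at 0 h and 73.3 ± 1.96 TPM at 6 h. In induced cells it went from 71.4 ± 4.45 to 23.6 ± 4.19 TPM (slope difference -0.22, SE 0.0389, adjusted p = 0.00807).

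C16orf91 was at 87.9 ± 1.06 TPM in uninduced and 27.6 ± 2.74 TPM in induced cells at 6 h (slope difference -0.24, adjusted p = 0.0263). NXT1, a cofactor of mRNA export, was at 132.3 ± 18.6 against 44.8 ± 5.75 TPM (-0.23, adjusted p = 0.0361), and DUSP1 at 151.6 ± 30.4 against 59.4 ± 1.51 TPM (-0.19, adjusted p = 0.0263). The noncoding RNAs LINC00920 (-0.26, adjusted p = 0.0263), MIR22HG (-0.24, adjusted p = 0.0188) and PITPNA-AS1 (-0.22, adjusted p = 0.0228) were also lost faster in the induced arm. HRH1, a histamine receptor, had a slope difference of -0.19 (adjusted p = 0.0484), which became 0.077 when transcripts were tested in place of genes. The paralog TOB1 was at 110.8 ± 10.4 against 66.9 ± 12.4 TPM at 6 h (-0.17, SE 0.0356, adjusted p = 0.0311). NFE2L2, which encodes the antioxidant regulator NRF2, and BMP2, a bone morphogenetic protein, had slope differences of -0.18 each and were chosen after their values were seen.

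**Figure D2:**
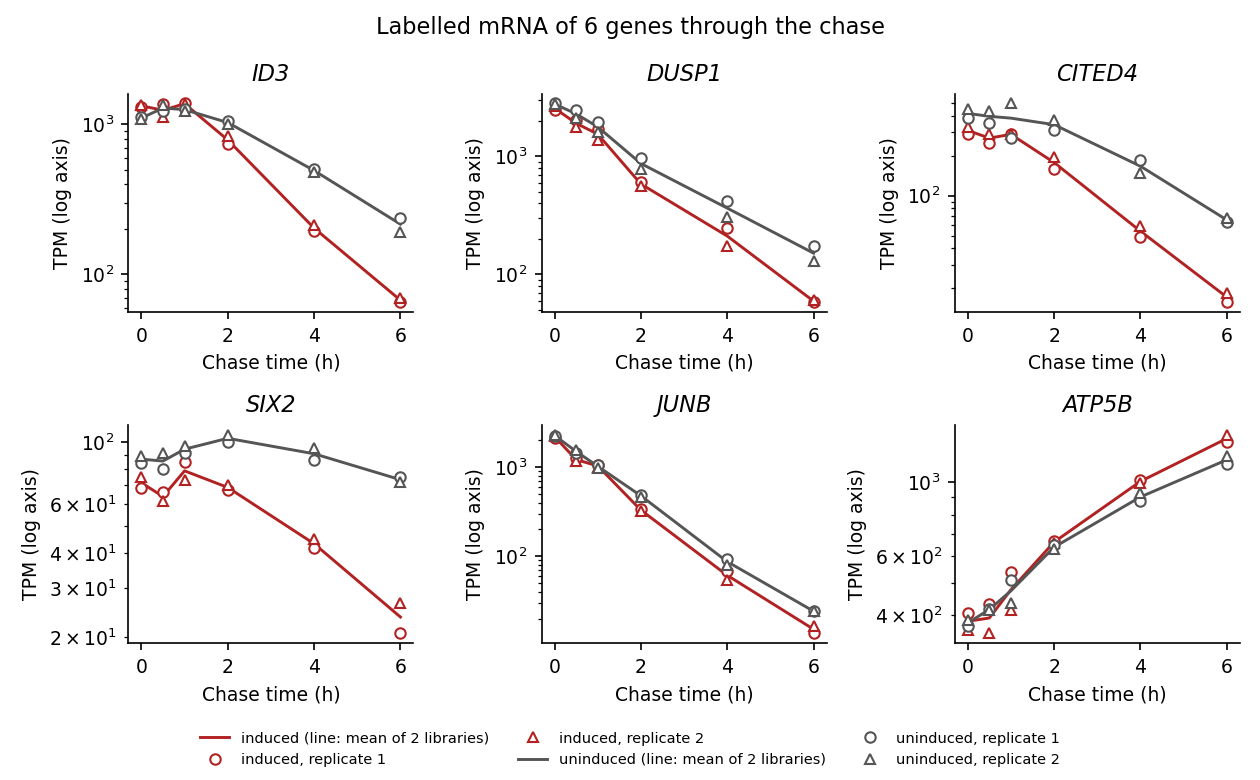
TPM on a log axis against hours of chase for ID3, DUSP1, CITED4 and SIX2, which had a slope difference past the threshold, and for JUNB and ATP5B, with each library as a point and the mean of 2 libraries as a line for each arm. ID3 ended at 67.4 ± 2.75 TPM in induced and 216.5 ± 32.7 TPM in uninduced cells (SD, n = 2).

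Immediate early genes were lost faster in the induced arm as a group, with a median slope of -0.53 log2 per hour against -0.39 in the uninduced arm. The slope difference passed in 4 of 43 members, all downward, and in 9 adjusted over the list alone. The 4 were ID3, DUSP1, the small GTPase RHOB (-0.19, adjusted p = 0.0228) and the transcription factor MAFF (-0.14, adjusted p = 0.049). The median slope difference was -0.0999 and 3 of 43 members lay above the median of all genes (adjusted p = 5.19e-11, and adjusted p = 0.0472 with an estimated correlation). The mRNAs of oxidative phosphorylation were relatively better kept, with a median slope difference of 0.0442 and 73 of 75 members above the median of all genes (adjusted p = 1.05e-16, and adjusted p = 0.0402 with an estimated correlation). In limma, 0 of these 75 passed alone, nor did any adjusted over the list alone, and NDUFA7 (0.14, adjusted p = 0.119) and UQCRH (0.061, adjusted p = 0.16) had the smallest p. These were the 2 lists that held with an estimated correlation, and fry called the same 2 (adjusted p = 0.00226 and 0.00863).

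Other lists passed with the preset correlation alone. Ribosomal protein mRNAs had a median of 0.044 and 77 of 79 members above the median of all genes, with 0 past the threshold alone in limma and 2 rising adjusted over the list alone (adjusted p = 1.02e-23, and adjusted p = 0.222 with an estimated correlation). Medians were 0.050 for glycolysis (adjusted p = 8.36e-07, and adjusted p = 0.355 with an estimated correlation) and 0.039 for the proteasome (adjusted p = 7.82e-08, and adjusted p = 0.355 with an estimated correlation). They were 0.038 for translation factors with oligopyrimidine tracts (adjusted p = 4.67e-06, and adjusted p = 0.419 with an estimated correlation) and 0.035 for the matrix (adjusted p = 0.00173, and adjusted p = 0.472 with an estimated correlation). They were 0.028 for lysosomal proteins (adjusted p = 0.000689, and adjusted p = 0.419 with an estimated correlation) and 0.031 for cholesterol synthesis (adjusted p = 0.00706, and adjusted p = 0.511 with an estimated correlation). Mitotic mRNAs had a median of 0.020 (adjusted p = 0.000107, and adjusted p = 0.498 with an estimated correlation). Histones had a median of 0.029, which became -0.0033 under quantile normalization (adjusted p = 4.67e-06, and adjusted p = 0.472 with an estimated correlation).

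Downward lists were p53 targets, zinc finger mRNAs and decay regulators. For p53 targets the median was -0.051, with 0 of 27 members past the threshold in limma and 4 falling adjusted over the list alone (adjusted p = 0.000312, and adjusted p = 0.419 with an estimated correlation). Zinc finger mRNAs had a median of -0.033, and ZNF576 (-0.15) and ZNF251 (-0.13) were the 2 of 392 past the threshold, against 3 adjusted over the list alone (adjusted p = 0.000227, and adjusted p = 0.511 with an estimated correlation). Decay regulators had a median of -0.055, with TOB2 (the transgene's reads included) up and TOB1 down, and 1 up and 3 down adjusted over the list alone (adjusted p = 0.0451, and adjusted p = 0.511 with an estimated correlation). In that list the AU-rich element binding proteins ZFP36L1 (-0.17, adjusted p = 0.0571) and ZFP36L2 (-0.15, adjusted p = 0.13) were not past the threshold.

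**Figure D3:**
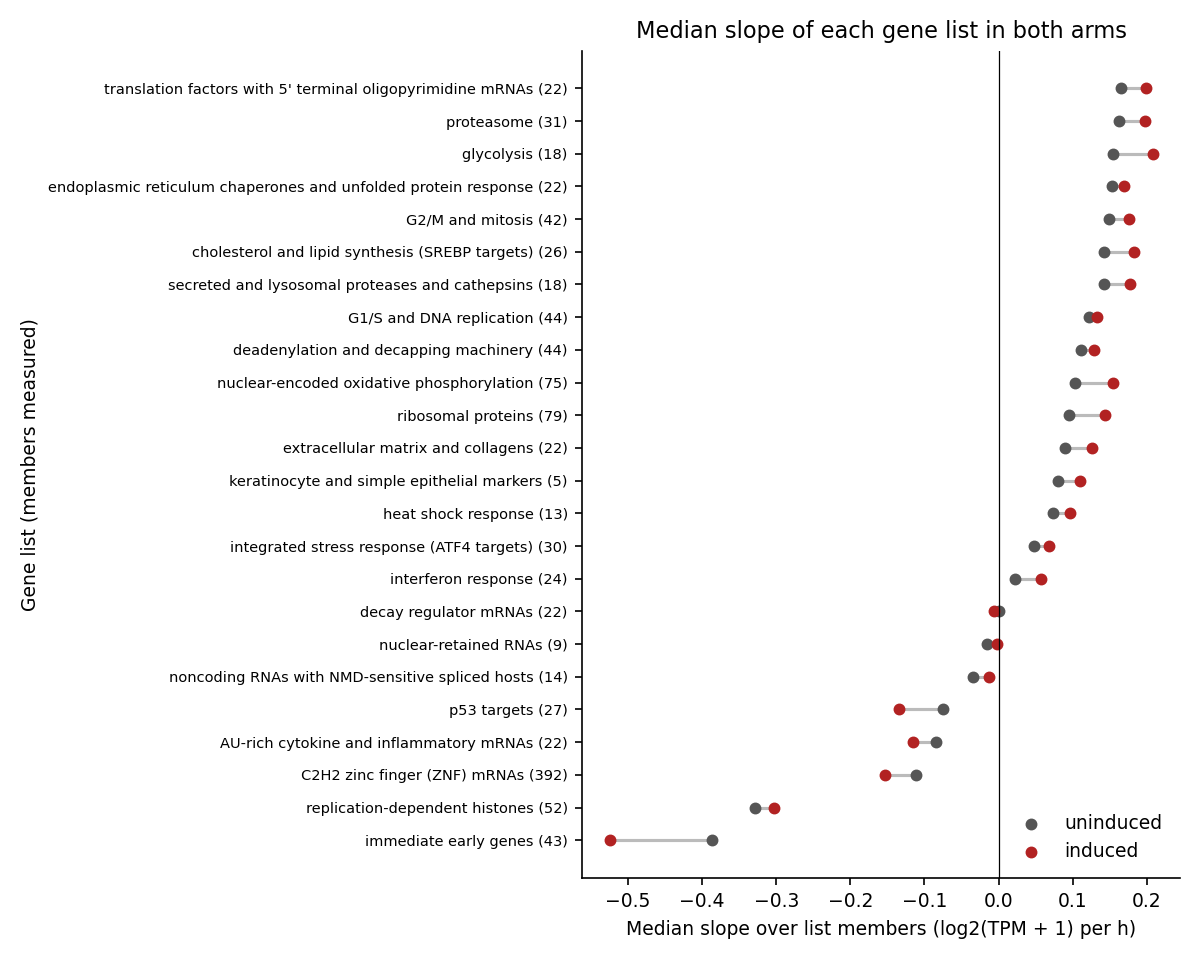
Median slope over the members of each gene list, in log2 of TPM plus 1 per hour, with a grey point for the uninduced and a red point for the induced arm and the number of measured members beside each name. Immediate early genes went from -0.39 to -0.53, and the uninduced medians of decay regulators, heat shock, ATF4 target, interferon and nuclear-retained lists changed sign under at least 1 other scaling.

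Over all genes, 46 of 13416 had a slope difference past the threshold, and 1673 had an unadjusted p under 0.05. TOB2 alone was higher, and 45 were lower, from -0.336 to -0.113 log2 per hour. The higher and lower counts were 11 and 93 after median-of-ratios scaling, 18 and 161 after quantile normalization and 36 and 787 with a trend contrast of the group means. They were 4 and 324 without RMRP, MIR6723 and RPPH1 and 4 and 396 with protein-coding transcripts. Of the 46 genes, 37 were still called after median-of-ratios scaling. Of those 45, 30 were falling, 3 rising and 12 without a slope past the threshold in uninduced cells, and 44 were falling in induced cells. Genes falling in uninduced cells had a median slope difference of -0.038, with 77.3% below 0, and rising genes had one of 0.0078, with 43.2% below 0. The count was 0 in limma without replicate 1 (550 at an unadjusted p under 0.05) and without replicate 2 (1517), and 0 over a chase of 0 to 4 h (947). It was 8 without induced 6 h replicate 1, 164 without induced 0 h replicate 2 and between these without any other library, and it was 7 for transcripts in place of genes.

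The spread of slopes asks whether decay differences between genes were wider in the induced arm, as a proportional speeding of decay would make them. The standard deviation of slopes across 13416 genes, free of replicate noise, was 0.147 log2 per hour in uninduced and 0.171 in induced cells. The variance ratio was 1.356 (exact two-sided permutation p = 0.0356 over 4096 swaps). In induced cells 42 of 43 immediate early genes fell and 69 of 75 mRNAs of oxidative phosphorylation rose. On an axis of decay built from the uninduced slopes of the other replicate, induced libraries led by -0.0205 h ± 0.252 at 0 h and by 0.742 h ± 0.407 at 4 h and 0.585 h ± 0.156 at 6 h (SD, n = 2). The ratio's permutation p rose above the threshold without some single libraries, to 0.277 at the highest, and was 0.106 for genes of at least 5 TPM.

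**Figure D4:**
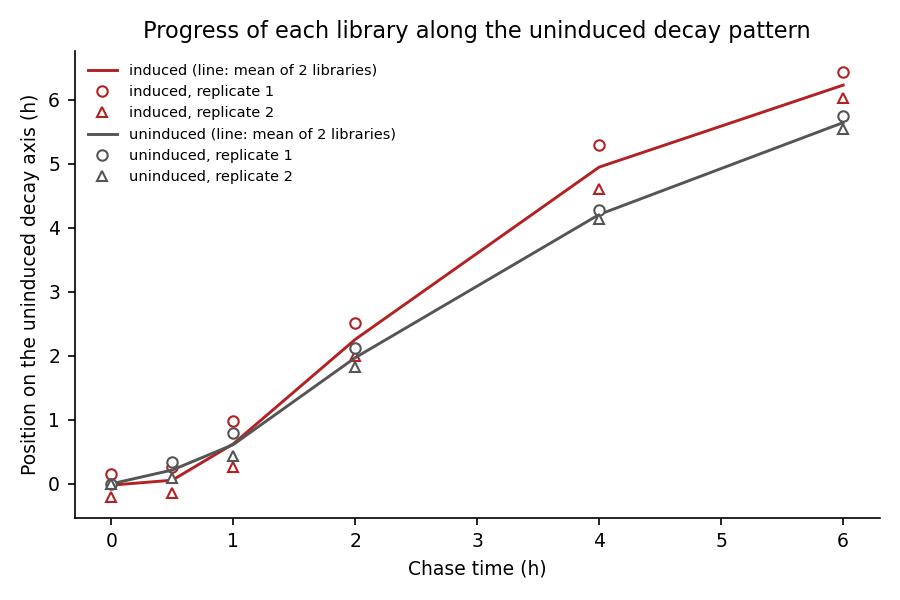
Position of each library in hours along the decay axis of the uninduced arm against hours of chase, with each library as a point and the mean of 2 libraries as a line for each arm. Induced libraries stood at 4.94 h on average after 4 h of chase and uninduced libraries at 4.2 h.

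The 0 h difference shows how labelled RNA stood at the start of the chase, 2 libraries against 2. CD55, a complement inhibitor on the cell surface, was at 156.3 ± 5.11 TPM in uninduced and 260.5 ± 7.83 TPM in induced cells (SD, n = 2; log2 difference 0.73, SE 0.108, adjusted p = 0.026). IRF2BP1, a transcriptional corepressor, was at 149.4 ± 6.75 against 97.9 ± 0.368 TPM (-0.60, SE 0.0973, adjusted p = 0.0367). TOB2 was higher by 1.18 (SE 0.163, adjusted p = 0.0228). IL23R, a cytokine receptor chain below 5 TPM that was named after its values were seen, was at 0.055 ± 0.00707 against 2.27 ± 1.03 TPM. These 4 of 13416 genes passed, 3 higher and 1 lower, with 881 at an unadjusted p under 0.05. Without induced 0 h replicate 1 the count in limma was 0, with 665 at an unadjusted p under 0.05.

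Replication-dependent histones were lower at 0 h as a group, with a median of -0.36 and a summed level of 62430 ± 3860 TPM in induced against 80240 ± 3030 TPM in uninduced cells (SD, n = 2). In limma 0 of 52 passed over all genes and 33 fell adjusted over the list alone (adjusted p = 1.33e-35, and adjusted p = 0.0745 with an estimated correlation), with HIST1H4E at -0.47 (adjusted p = 0.0613). AU-rich mRNAs had a median of 0.23 (adjusted p = 0.00129, and adjusted p = 0.374 with an estimated correlation), with the cytokine LIF at 0.36 (adjusted p = 0.509). Cholesterol synthesis mRNAs had a median of 0.22 (adjusted p = 6.45e-05, and adjusted p = 0.615 with an estimated correlation), with the desaturase SCD at 0.64 (adjusted p = 0.458). Downward medians were -0.093 for ribosomal proteins (adjusted p = 1.5e-09, and adjusted p = 0.615 with an estimated correlation) and -0.098 for mitosis (adjusted p = 7.42e-06, and adjusted p = 0.615 with an estimated correlation). They were -0.053 for G1/S (adjusted p = 0.000235, and adjusted p = 0.644 with an estimated correlation) and -0.081 for the proteasome (adjusted p = 0.000535, and adjusted p = 0.644 with an estimated correlation). ATF4 targets were at -0.10 (adjusted p = 0.0298, and adjusted p = 0.644 with an estimated correlation) and noncoding hosts of small nucleolar RNAs at -0.068 (adjusted p = 0.0443, and adjusted p = 0.615 with an estimated correlation). For transcripts in place of genes, the mean of those hosts less the mean of all transcripts tested was positive, at 0.00931. Zinc finger mRNAs were called downward from a mean of -0.012 but had a median of 0.0022, which was -0.049 under median-of-ratios scaling and -0.045 under quantile normalization and 0.039 without RMRP, MIR6723 and RPPH1 (adjusted p = 0.0298, and adjusted p = 0.703 with an estimated correlation). For each of these 9 lists, 0 members passed in limma, over all genes or adjusted over the list alone.

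The mean difference over the 6 times compares the level of labelled RNA between the arms, 12 libraries against 12. Its p-values treat these libraries as independent. The 6 times of an arm and replicate number may share effects, and each arm held 2 such series, so the p-values may be too small. By camera with the preset correlation, histone mRNAs were lower in induced cells and mRNAs of cholesterol synthesis, the lysosome, the endoplasmic reticulum and the matrix were higher. None of these 5 calls held with an estimated correlation (adjusted p = 0.144, 0.527, 0.527, 0.563 and 0.563). MALAT1 and NEAT1, long noncoding RNAs retained in the nucleus, were higher in both induced libraries than in both uninduced libraries at each of the 6 times, at 377.4 against 194.3 TPM and 290.6 against 170.6 TPM on average. Their log2 differences were 0.96 (SE 0.0983, adjusted p = 5.59e-06) and 0.82 (SE 0.0673, adjusted p = 8.08e-07). TOB2 was higher by 1.66 (SE 0.0665, adjusted p = 2.12e-10).

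Lower in induced cells were TIGD5 (-1.03, SE 0.0851, adjusted p = 8.08e-07), C9orf69 (-0.90, adjusted p = 9.72e-08) and ADAT3, a subunit of a tRNA adenosine deaminase (-0.88, adjusted p = 1.08e-06), each lower in both induced libraries than in both uninduced libraries at each of the 6 times. CITED4 (-0.96, adjusted p = 1.88e-06), TPGS1 (-0.91), LOC642423 (-0.89), NBL1, an antagonist of bone morphogenetic proteins (-0.82), and FKBPL (-0.81) were lower too. Short RNAs again reached the extremes, with SNORD11 (1.32), SNORD72 (0.97) and SNORA77 (0.84) higher and MIR6126 (-1.85) and SNORA60 (-1.19) lower. SNORD11 differed by 2.37 in replicate 1 and 0.28 in replicate 2. The humanin-like genes MTRNR2L2 (0.86), MTRNR2L9 and MTRNR2L6 were higher mainly in replicate 2.

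Of 52 histones, 47 fell and 0 rose, with the same counts adjusted over the list alone, and the median was -0.34 (adjusted p = 3.88e-29, and adjusted p = 0.144 with an estimated correlation). HIST1H2BJ was at -0.45, HIST1H4E at -0.38 and HIST1H3H at -0.50. Of 44 G1/S and replication mRNAs, 15 fell and 0 rose, also adjusted over the list alone (adjusted p = 8.94e-05, and adjusted p = 0.627 with an estimated correlation), with the flap endonuclease FEN1 at -0.35 and the licensing factor CDT1 at -0.37. Of 43 immediate early genes, 16 fell and 3 rose (17 and 3 adjusted over the list alone), with ID3 at -0.49, JUNB at -0.34, DUSP1 at -0.55 and the clock-linked repressor BHLHE40 at 0.36 (adjusted p = 0.000615, and adjusted p = 0.527 with an estimated correlation). Of 392 zinc finger mRNAs, 100 fell and 24 rose (102 and 28 adjusted over the list alone), as ZNF787 did at -0.54 and ZNF48 at -0.71 (adjusted p = 1.4e-06, and adjusted p = 0.563 with an estimated correlation). Of 30 ATF4 targets, 9 fell and 2 rose, also adjusted over the list alone, with the glutathione-degrading enzyme CHAC1 at -0.57 and the stress factor DDIT3 at -0.29 (adjusted p = 0.0172, and adjusted p = 0.683 with an estimated correlation). Of 79 ribosomal protein mRNAs, 10 fell and 0 rose (6 and 0 adjusted over the list alone), with a median of -0.058 that became 0.0030 under quantile normalization (adjusted p = 5.48e-05, and adjusted p = 0.563 with an estimated correlation). Of 42 mitotic mRNAs, 6 fell and 2 rose (5 and 2 adjusted over the list alone), with the survivin gene BIRC5 at -0.20 and CENPF at 0.17 (adjusted p = 0.0455, and adjusted p = 0.683 with an estimated correlation). Of 14 noncoding hosts of small nucleolar RNAs, 5 fell and 2 rose, also adjusted over the list alone, with SNHG7 at -0.30 (adjusted p = 0.0322, and adjusted p = 0.563 with an estimated correlation).

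Of 26 mRNAs of cholesterol and lipid synthesis, 17 rose and 0 fell (18 and 0 adjusted over the list alone), and the median was 0.23 (adjusted p = 1.15e-06, and adjusted p = 0.527 with an estimated correlation). SCD, the stearoyl-CoA desaturase, was at 728.1 against 442.7 TPM on average (0.68), and the sterol transporter STARD4 at 0.33. Of 18 lysosomal and protease mRNAs, 9 rose and 0 fell (14 and 0 adjusted over the list alone), with LAMP2 at 0.34 and the cathepsin CTSB at 0.35 (adjusted p = 6.47e-05, and adjusted p = 0.527 with an estimated correlation). Of 22 endoplasmic reticulum mRNAs, 10 rose and 1 fell (12 and 2 adjusted over the list alone), with the chaperone HSPA5 at 0.34 and DNAJC3 at 0.25 (adjusted p = 0.00349, and adjusted p = 0.563 with an estimated correlation). Of 22 matrix mRNAs, 8 rose and 0 fell, also adjusted over the list alone, with the protease inhibitor TIMP1 at 0.38 and PLOD2 at 0.37 (adjusted p = 0.00377, and adjusted p = 0.563 with an estimated correlation). Of 22 AU-rich mRNAs, 5 rose and 0 fell, also adjusted over the list alone, with LIF at 0.32 and SOD2 at 0.25 (adjusted p = 0.0205, and adjusted p = 0.527 with an estimated correlation).

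In total, 3454 of 13416 genes had a mean difference past the threshold, 1922 higher and 1532 lower, with the libraries of an arm treated as independent. The higher share was 55.6%, against 67.7% with protein-coding transcripts alone and 65.8% without RMRP, MIR6723 and RPPH1. The majority turned to lower genes after median-of-ratios scaling (46.0% higher), after quantile normalization (48.7%), for transcripts in place of genes (42.1%) and in a fit that ignored time (47.6%). The count was 252 in a fit of 2 groups that ignored time and 1811 for transcripts in place of genes. In the comparisons of level, 0 lists held in camera with an estimated correlation, at 0 h or over the 6 times, and fry called 1 list at 0 h and 11 over the 6 times.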

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

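The slope differences and the spread of slopes were planned, and the tests of explanations here, with the counts over other splits of the libraries, were chosen after the results were seen.

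Some genes changed along the chase at different rates in the 2 arms, by a test of the difference itself. The slope of TOB2 was higher in induced cells, with a difference of 0.2236 log2 per hour. Reads of the transgene and of the cell's own TOB2 are pooled there, so this need not mean that the same mRNA was better kept. No other gene was called upward in the main fit, but the upward calls were 11 after median-of-ratios scaling, 18 after quantile normalization and 36 with a trend contrast of the group means. The genes lost faster in induced cells included ID3 (-0.3364), CITED4 (-0.2717), LINC00920 (-0.2567), C16orf91 (-0.244) and MIR22HG (-0.242). NXT1 (-0.2304), SIX2 (-0.225), PITPNA-AS1 (-0.2171), DUSP1 (-0.1937) and HRH1 (-0.1883) were lost faster as well. In all, 46 genes differed, of which 37 were still called after median-of-ratios scaling. Among gene groups, immediate early genes (median slope difference -0.0999) and mRNAs of oxidative phosphorylation (0.0442) moved apart between the arms. Genes falling past the threshold in uninduced cells had a median of -0.0377, and rising genes one of 0.00776. Lists matched to the histones on uninduced slope and level had one of -0.0904. Whether these 2 groups differ from genes of similar uninduced slope was not tested.

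For the count of 46 genes, 3 of 100 splits of the libraries within each time gave as many, the real split included. That share is small, but the count did not lie beyond the range of the other splits, of which 2 called 106 and 140 genes. Chance is therefore not excluded. The count was also 0 in limma without either replicate series (550 and 1517 at an unadjusted p under 0.05), where 12 libraries were left. Counts well above the real one point to a structure of the libraries, which may be the arms themselves. The split with 140 genes placed 16 of the 24 libraries as the arms do and 14 as the replicate numbers do. Among the 99 other splits, those with 32, 106 and 140 genes ranked 4, 5 and 5 by how far their match with the arms changed along the chase, so differences in level between the arms may have entered their slopes. The splits ranked 1, 2 and 3 called 0 genes in limma, so this was not established. Chance cannot be excluded for the number of lists called with a preset correlation, where 8 of 100 splits reached the real 14 and the highest other split reached 16.

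The spread of slopes was wider in induced cells, with a variance ratio of 1.356. A fixed head start of the induced arm would show in the first hour of chase too, but the lead along the uninduced decay pattern grew by 0.72 h from the first hour to 4 and 6 h (0.77 h in replicate 1 and 0.669 h in replicate 2), which argues against it as the whole cause. Dilution by RMRP, MIR6723 and RPPH1 moves the slopes of all genes by about the same amount, with a median of -0.00897 log2 per hour for the slope difference, which hardly alters a spread. The ratio was 1.357 without those RNAs (exact permutation p = 0.0342), which by itself decides nothing. An effect of doxycycline and an effect of the TOB2 mutant cannot be told apart, because the drug was in the medium of the uninduced arm alone. The list of ATF4 targets, read as a sign of drug stress, had an adjusted p = 0.644 with an estimated correlation at 0 h, which decides nothing.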

How the results depend on the processing

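Removal of RMRP, MIR6723 and RPPH1, restriction to protein-coding transcripts and swaps not limited by replicate number were chosen after the data were seen, and the other alternatives were planned. The 2 lists that held for the slope difference with an estimated correlation were immediate early genes and oxidative phosphorylation. That test was run on the main fit alone. With the preset correlation, both lists kept their direction and their call under each alternative and each left-out library that was run. Over these settings, values of named genes kept direction and call 311 times for the slope difference and kept direction without passing 125 times, and 580 and 152 times for the mean difference. Against 46 genes, the slope difference was past the threshold for 88 with a pseudocount of 0.1, 25 with a pseudocount of 5, 30 without a filter and 84 at a mean of at least 5 TPM. It was 179 after quantile normalization, 104 after median-of-ratios scaling, 823 with a trend contrast of the group means (787 lower), 328 without those 3 RNAs and 400 with protein-coding transcripts. It was 7 for transcripts, and in limma 0 over 0 to 4 h (947 at an unadjusted p under 0.05) and 0 over 0 to 2 h (190). Fewer libraries entered the shorter chases. The trend contrast gives the same slope differences as the line fit, so its count differs through the error alone. Its error comes from the spread within groups (12 residual degrees of freedom). In the line fit (20), departures from a straight line enter the error too. For the other alternatives the cause was not tested. Without replicate 1 and without replicate 2 it was 0 (550 and 1517 unadjusted), with 12 libraries left. Leaving out 1 library gave 8 to 164, from induced 6 h replicate 1 to induced 0 h replicate 2. In replicate 1 it was 19 without uninduced 0 h, 30 without 0.5 h, 29 without 4 h and 18 without 6 h. In replicate 2 it was 18, 30 and 117 without uninduced 0, 4 and 6 h, and 88 and 19 without induced 4 and 6 h.

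The 0 h count of 4 was 7 after quantile normalization, 2 without a variance trend, 254 for intercepts of the lines, 8 without the 3 RNAs and 10 with protein-coding transcripts, and the cause was not tested. Leaving out 1 library gave 0 to 5. It was 0 without induced 0 h replicate 1 (665 unadjusted in limma) and 1 without uninduced 0 h replicate 1. It was 2 without any of uninduced 1, 2 or 4 h or induced 4 h of either replicate, or uninduced 0 h replicate 2. The variance ratio of 1.356 missed the threshold at 1.351 with a pseudocount of 5 (exact permutation p = 0.102), 1.371 at a mean of at least 5 TPM (0.106), 1.421 after quantile normalization (0.0522), 1.371 over 0 to 4 h (0.0547), 1.138 over 0 to 2 h (0.305) and 1.391 with protein-coding transcripts (0.11), and the cause was not tested. Without 1 library it was 1.233 to 1.57. It missed the threshold without uninduced 0 h (1.348) or 6 h (1.233) or induced 0.5 h (1.314), 1 h (1.341) or 4 h (1.288) of replicate 1. In replicate 2 these values were 1.314, 1.238, 1.339, 1.325 and 1.315. The slope counts over 0 to 2 h were 3008 uninduced and 3826 induced, with fewer libraries. Leaving out libraries gave 6690 to 8844 and 7917 to 9528. The mean difference gave 1811 for transcripts, 252 in the fit ignoring time, where differences between times enter the spread, and 2625 to 3983 without 1 library.

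List calls for the uninduced slope were 2 with an estimated correlation, and 16 to 18 with libraries left out. For the slope difference they were 9 for transcripts, 2 with an estimated correlation, 2 with fry and 11 to 16 with libraries left out. For 0 h they were 6 for transcripts, 0 in camera with an estimated correlation, 1 with fry and 4 to 14 with libraries left out, with 6 without uninduced 0 h replicate 2 and 4 without induced 0 h replicate 2. For the mean difference they were 8 in the fit ignoring time, 0 in camera with an estimated correlation and 11 to 14 with libraries left out. List values here are the mean of the list less the mean of all genes. Quantile normalization reversed this value to -0.00221 for the histone slope difference and to 0.00446 for the ribosomal mean difference. Tests of transcripts reversed the slope difference of HRH1 to 0.07724 and the 0 h list value of hosts of small nucleolar RNAs to 0.00931. The cause was not tested. With the replicate number as a block, 99 genes passed for the slope difference and 11 at 0 h, and 4721 against 3454 passed for the mean difference. Deviations of libraries sharing a number correlated across genes at 0.0203 to 0.156 over the 6 times, and 29 of 66 pairs of groups were above 0.1. The models did not pair the libraries by number, as was fixed before the data were examined. Replicate 2 had a lower median-of-ratios scaling factor than replicate 1 in every group, so some structure by replicate number was present and was left out of the main models. The slopes and swaps of the planned test of spread and the decay axis did match libraries by number. With swaps not limited by it, the variance ratio of 1.356 had a permutation p = 0.0149. Scaling on spike-ins or mitochondrial transcripts was not run, since the table holds neither. The spread was not computed with the block, and the spread and the group means were not computed with a whole replicate series left out. Depth is unknown, so it cannot be said which low values were limited by it.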

Other observations

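The comparisons of further gene lists were planned, and the tests of explanations and of neighbouring genes were chosen after the results were seen.

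Several lists without a call in camera held members that changed in level between the arms. Over all genes, 1922 of 13416 were higher and 1532 lower, so such members alone do not set a list apart. Fry called 3 of these lists, nuclear-retained RNAs (adjusted p = 0.000839), mRNAs of oxidative phosphorylation (0.00386) and epithelial markers (0.00933), all upward. Fry does not compare a list with other genes. The oxidative phosphorylation median was 0.0755, against 0.0507 for all genes, with 45 of 75 members above the latter. Of 9 nuclear-retained RNAs 4 rose and 2 fell. Among markers of simple epithelia, KRT8 (mean difference 0.42, adjusted p = 0.00044) and KRT7 (0.33) rose in 2 of 5 measured members and 0 fell. Among interferon response genes, 3 of 24 rose and 0 fell, with the antiviral factors IFIT1 at 0.33 and OAS1 at 0.31 and the class I light chain B2M at 0.19. Of 27 p53 targets, 8 fell and 5 rose, with the nuclease AEN at -0.37, PHLDA3 at -0.34 and BTG2 at -0.50, while the cell cycle inhibitor CDKN1A rose by 0.34. Of 13 heat shock genes, the cochaperone DNAJB1 (-0.39) and the chaperone HSPA8 (-0.33) fell and HSPB1 rose (0.22), and the list's median of -0.013 became 0.0072 without RMRP, MIR6723 and RPPH1. Among decay regulators 3 of 22 rose, TOB2 with the transgene's reads among them, and 3 fell. The AU-rich element binding protein ZFP36 was at -0.36 and the cytoplasmic polyadenylation factor CPEB4 at 0.26. The deadenylation and decapping list had 6 of 44 higher and 2 lower, with the exosome subunit EXOSC3 at -0.26 and the surveillance kinase SMG1 at 0.25. Of 75 mRNAs of oxidative phosphorylation 11 rose and 0 fell, and of 18 glycolytic mRNAs 3 rose and 1 fell, with PKM at 0.39. Proteasome mRNAs had 0 of 31 past the threshold in limma, also adjusted over the list alone. In the translation factor list 2 of 22 members rose, among them EIF2S3 at 0.21. Adjusted over the list alone, the counts of rising and falling members became 3 and 1 for epithelial markers, 1 and 3 for heat shock, 6 and 1 for deadenylation and decapping, and 4 and 0 for oxidative phosphorylation.

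Among lists without a call in camera for the uninduced slope, fry called interferon genes (adjusted p = 0.00226) and epithelial markers (5.7e-05) upward and hosts of small nucleolar RNAs (0.0329) and nuclear-retained RNAs (0.000116) downward. Upward here is relative to 0 and not to other genes, whose median slope was 0.0389. The interferon median of 0.0218 was lower than that, with 11 of 24 members above it. Of 22 decay regulators 10 rose and 8 fell, with ZFP36 at -0.65 log2 per hour, BTG2 at -0.68 and the RNA-binding proteins KHSRP at 0.32 and ELAVL1 at 0.20. Of 30 ATF4 targets 14 rose and 8 fell, with DDIT4 at -0.61 and CHAC1 at -0.74. Of 13 heat shock genes 7 rose and 5 fell, with DNAJB1 at -0.39 and the mitochondrial chaperonin HSPD1 at 0.22. The medians of these 3 lists, and of the interferon and nuclear-retained lists, changed sign under at least 1 scaling. Adjusted over the list alone, 15 ATF4 targets rose and 9 fell, and the counts of the other lists here were the same. Interferon genes rose in 7 of 24 cases and fell in 1, and hosts of small nucleolar RNAs fell in 6 of 14 and rose in 3, with SNHG12 at -0.40. Of 9 nuclear-retained RNAs 4 rose and 4 fell, with MALAT1 at 0.12 and NEAT1 at -0.54, and of 5 epithelial markers 3 rose and 1 fell.

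For the 3454 genes with a mean difference, 1 of 100 splits, the real one, gave as many, and the highest other gave 221. A random mix of the libraries within each time is thus argued against. The splits shuffled each time separately, which breaks up any difference shared by all times of an arm and replicate number. Chance differences between such series are therefore not excluded. Chance cannot be excluded for the 13 lists either, since 13 of 100 splits gave as many and the highest other gave 15.

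A candidate explanation for the wider slopes in induced cells is a faster loss of polyadenylated mRNAs alone, as a deadenylation factor could bring about. Histone mRNAs, which lack a poly(A) tail, would then escape it. Their median slope difference was 0.0295, against -0.0904 for 10000 random lists matched on uninduced slope and level (95% of lists from -0.11 to -0.0609), a gap of 0.12 log2 per hour. That range is too narrow for a family of genes that move together, with an estimated correlation of 0.369, and the list's own call was lost with an estimated correlation (adjusted p = 0.472). Over 1000 splits of the libraries within each time, which keep that correlation, 2 gave a gap as far from 0, the real one included (permutation p = 0.002). These splits shuffled each time separately, which breaks up any drift shared by the times of an arm and replicate number. They therefore cannot exclude chance differences between such series. The gap had the same sign in both replicates, with 0.0187 against -0.109 in replicate 1 and 0.038 against -0.0729 in replicate 2. The direction is the one that the hypothesis predicts. Chance differences between series, doxycycline and a change in histone mRNA decay of its own are not excluded. The histone median itself became -0.0033 under quantile normalization.

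MALAT1 and NEAT1 were higher in induced cells. A shift in library composition is argued against, since MALAT1 was still higher by 0.925 (SE 0.0777) and NEAT1 by 0.779 (SE 0.066) after median-of-ratios scaling. More nuclear RNA in the cytoplasmic fraction of induced cells may raise both and cannot be told apart from other causes. The 7 other RNAs of the nuclear list had a median of 0.0174, with KCNQ1OT1 (0.355, adjusted p = 0.00352) and SCARNA2 (0.224, adjusted p = 0.0204) higher and RPPH1 (-0.184) and HCG18 (-0.159) lower. An effect of the mutant or of doxycycline on these RNAs was not tested.

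Replication-dependent histones were lower in induced cells, with 47 of 52 past the threshold, but the list's call was lost with an estimated correlation (adjusted p = 0.144). Reads split between near-identical copies are argued against, since the TPM summed over the family was lower in both induced libraries than in both uninduced libraries at each of the 6 times, by a mean log2 ratio of -0.332 (-0.262 in replicate 1 and -0.402 in replicate 2). Composition is argued against, since the median was -0.378 after median-of-ratios scaling. Fewer cells in S phase could lower histone mRNAs, as an antiproliferative protein might bring about, but the G1/S list had a median of -0.0475 with 15 of 44 members lower, which leaves this open. An effect of the mutant on histone synthesis was not tested apart from the drug.

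Genes that were higher in induced cells were neighbours more often than random genes. Neighbours were consecutive in order along a chromosome among the 10230 genes with a known position and a mean of at least 5 TPM. No limit on distance was set, so other genes may lie between them. Among the 200 genes with the largest higher mean difference, 12 pairs were neighbours, against 3.85 on average for random sets drawn from 10230 genes (permutation p = 4e-04). For the 200 genes with the largest lower difference there were 12 pairs against 3.87 (permutation p = 5e-04). Pairs included C4BPB and CD55, S100A6 and S100A4, S100A4 and S100A16, and SCD and LINC00263 among higher genes, and ZNF48 and ZNF771 and HIST1H2BJ and HIST1H2AG among lower genes. A candidate explanation is a change at single loci, but overlapping transcripts, shared reads and clusters of related genes could give such pairs too and were not tested.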
